A study of Mus musculus with 9 samples.

How the data were processed

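Group 2 innate lymphoid cells (ILC2s, tissue-resident lymphocytes that make type 2 cytokines) came from the fat-associated lymphoid clusters of wild-type C57BL/6 mice. They were cultured for 48 h with IL-33, with IL-33 and IFN-γ, or with IL-33 and IL-27, each cytokine at 10 ng/ml. RNA was extracted with an Allprep DNA/RNA Micro kit and libraries were made with the TruSeq RNA v2 low sample protocol. Per the submitters' processing notes, the reads were processed with Bowtie2 2.1.0, TopHat2 2.0.8 and Cufflinks 2.1.1 against mouse genome build mm9, with no roles or parameters stated and the gene annotation not named. The deposited tables give 1 value per gene and library. The unit, FPKM (fragments per kilobase of transcript, normalised by the authors to the number of mapped fragments), is not written in the deposited tables. It was inferred from Cufflinks being named, from a Cufflinks column header and from decimal values that are never negative and whose sums differ between libraries. The replicate 3 tables of all 3 groups hold values with 1 decimal and a comma that groups digits, which was removed before reading; the other tables hold more decimals.

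Each of the 9 tables listed the same 23234 genes by symbol. Spreadsheet conversion had turned 25 symbols into dates, and these were kept as separate features without a name. A single match in the GENCODE vM1 annotation (build mm9) was found for 21640 symbols (93.1%), which gave the gene identifiers and coordinates, and 188 symbols matched more than once and received none. The authors' gene models may differ from these. All sample columns were used. No read counts were analysed here. The depth of each library was therefore estimated from the regular steps between low values, a value of 1 fragment in a gene of known length being worth a fixed FPKM. The estimate was checked on simulated libraries of known depth, where it returned the simulated depth, but it rests on gene lengths of an annotation that is not the authors', so it is approximate.

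Values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 9 libraries were tested (11014 genes). All 3 groups were fitted together with limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend, two-sided) in R 4.3.3, without a covariate. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was the threshold, with no minimum fold. Log2 fold changes are differences of group means on the log2(FPKM + 1) scale with limma's standard error (SE), and folds are 2 to that power; they are smaller than ratios of FPKM for genes near 0. Group means of FPKM are given with the standard deviation (SD) of 3 libraries. Tables were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

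The labels number the libraries of each group 1 to 3 without saying whether equal numbers share a cell preparation. Each library's deviation from its group mean was therefore correlated with that of every library of another group, over the tested genes. The 9 pairs with the same number correlated at 0.128 to 0.367 and the 18 pairs with other numbers at -0.298 to -0.0251. The library identifiers in the tables also run consecutively within a number. Centring on group means makes correlations of other numbers negative on balance where same-number ones are positive, so they are not separate evidence. Among genes with a mean of at least 20 FPKM the lowest same-number correlation was 0.0332 and the highest of other numbers 0.0706. The numbers were taken to pair the libraries. A second limma fit with the replicate number as a block is given beside results as the blocked fit. The fit without the block, chosen before the data were examined, remained the reported one.

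A total of 34 gene lists with 595 entries was written before the data were examined. They covered interferon signalling and its target families, lymphocyte programmes, ILC2 products and receptors, metabolism, stress, proliferation, cell death and markers of other cell types; 579 entries were listed in the tables and 423 were tested. Lists with at least 2 tested members (28) were compared with all other genes by camera, with the preset inter-gene correlation of 0.01 and again with a correlation estimated from the data, and p-values were adjusted over the 28 lists of a comparison. Single genes of a list were also adjusted over the list alone. Named genes followed a rule also written beforehand. It took the 10 genes with the largest log2 fold change in each direction in each comparison with IL-33 (5 in the direct comparison of IFN-γ with IL-27), among genes past the threshold with non-overlapping groups and a mean of at least 5 FPKM in the higher group. It added a fixed set of cytokine, receptor, transcription factor and signalling genes. It also added up to 4 members with the smallest adjusted p of each list with a camera call or at least 3 called members, and the 2 most abundant members of each cell type and quality list. Genes named outside this rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

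The fit without the block was tested on simulated data with 200 genes changed. These were made from the unblocked spread of these libraries, without a replicate effect. A simulated 4-fold change was recovered in 79.0% of genes for the IFN-γ comparison and 85.5% for the IL-27 comparison, with 3.66% and 2.84% false calls among all calls. A simulated 2-fold change was recovered in 3.00% and 4.00%, without a false call. The correlation of log2 fold changes between the 2 comparisons, which share the same IL-33 libraries, was set against 50 simulations in which no group differed. The alternatives changed 1 choice at a time, except where 2 are named together. They were the pseudocount (0.1 or 5), the filter (none, or a mean of at least 5 FPKM), scaling (median of ratios, or quantile normalization), the replicate block, only the 2 groups compared in the fit, no intensity trend, and leaving out each library or each replicate number. A further 4 alternatives were chosen after seeing the data, namely leaving out small RNA features, the block with libraries 1 and 2, the block with quantile normalization, and the list tests with the block and an estimated correlation.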

Results

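Gene expression was measured by RNA sequencing in 9 libraries of cultured mouse ILC2s, with 3 libraries in each of 3 groups. The groups were IL-33 alone, IL-33 with IFN-γ and IL-33 with IL-27. IL-33 is an alarmin that activates ILC2s, IFN-γ is the type II interferon, and IL-27 is a cytokine of the IL-12 family. The labels do not say whether replicates were separate cultures or animals, so p-values measure the spread between these libraries, part of which may be technical. FPKM summed to between 628600 and 672500 per library, and between 10504 and 11004 genes had at least 1 FPKM. The steps between low values corresponded to about 925000 to 1035000 fragments per library. At that depth 1 fragment in a transcript of 2 kb was worth 0.483 to 0.541 FPKM, and the 3 fragments used as a limit for a listed 0 were worth 1.45 to 1.62 FPKM. Features named as small RNAs took 3.45% to 17.9% of the FPKM sum. Some fibroblast transcripts were higher in the replicate 3 libraries of all 3 groups than in the others. Col1a1, a collagen chain gene chosen after its values were seen, had 8.90 to 14.6 FPKM in those 3 libraries and at most 1.04 FPKM in the other 6, and Sparc, a matrix protein gene, had 12.9 to 28.2 FPKM against at most 1.35 FPKM. The matrix genes Col1a2 (3 to 12 FPKM against at most 0.209), Col3a1 (4.1 to 10.2 against at most 0.385) and Fn1 (2.6 to 5.7 against at most 0.502), also chosen after their values were seen, followed the same division. Among the 7 tested members of the fibroblast list, Lum and Dcn did not. Lum, a proteoglycan gene, had 16.85 FPKM in IL-33 replicate 1 and 1.0 to 3.2 FPKM in the replicate 3 libraries. Dcn, chosen after its values were seen, had 1.3, 12.8 and 1.2 FPKM in the replicate 3 libraries with IL-33, IFN-γ and IL-27. It had 1.297 and 1.172 FPKM in IL-27 replicates 1 and 2. Pearson correlations of log2(FPKM + 1) across genes were 0.869 to 0.926 between libraries of a group and 0.829 to 0.939 between groups.

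The comparison of IFN-γ with IL-33 alone asked what the interferon changed in IL-33-activated ILC2s. Genes of the interferon response were among the largest rises. Irf1, an interferon-induced transcription factor (chromosome 11, 53583516 to 53591876, build mm9), rose 11.3-fold from 51.5 ± 36.0 to 525 ± 153 FPKM (SD, n = 3; log2 fold change 3.49 ± 0.41 SE, limma adjusted p = 0.00182). Gbp2, an interferon-inducible guanylate-binding GTPase (chromosome 3, 142283566 to 142300972), rose 111-fold from 11.2 ± 4.63 to 1370 ± 617 FPKM (log2 fold change 6.79 ± 0.36 SE, adjusted p = 1.98e-05). Ccl5, a chemokine that attracts T cells (chromosome 11, 83339280 to 83344020), rose 130-fold from 5.06 ± 1.92 to 764 ± 147 FPKM (adjusted p = 2.82e-05).

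Of the 21 tested guanylate-binding proteins and immunity-related GTPases, which act in defence against intracellular microbes, 19 rose with IFN-γ, none fell and 2 did not pass, and 21 rose when adjusted over the list alone. Their mean log2 fold change was 4.50, and camera called the list higher (adjusted p = 1.72e-44, adjusted p = 0.0498 with an estimated correlation, 0.0639 with that correlation in the blocked fit). Gbp5 rose 45.5-fold, to 112 ± 15.4 FPKM (SD, n = 3). Iigp1 was listed at 0, 0 and 0.7 FPKM with IL-33 and rose to 54.9, 113 and 274 FPKM. Gbp6, Gbp10, Tgtp1 and Tgtp2 were also among the 10 largest rises, but Gbp6 and Gbp10, and Tgtp1 and Tgtp2, are close copies that share reads, so the split within each pair is uncertain. Of 35 antiviral interferon-stimulated genes, 18 rose and none fell (31 higher, adjusted over the list alone), among them Zbp1, a nucleic acid sensor, from 24.04 ± 14.1 to 314 ± 135 FPKM, and Parp14, from 5.96 ± 2.43 to 32.2 ± 1.64 FPKM. The mean log2 fold change of that list was 1.88 (camera adjusted p = 3.40e-28, adjusted p = 0.0666 with an estimated correlation, 0.0124 with that correlation in the blocked fit). Of 23 genes of STAT and IRF signalling, 7 rose and none fell (9 higher and 4 lower, adjusted over the list alone). Irf8 rose from 7.46 ± 2.48 to 71.6 ± 6.71 FPKM, and Socs1, a feedback inhibitor of cytokine signalling, from 5.50 ± 2.21 to 40.7 ± 9.63 FPKM (adjusted p = 7.07e-04). Socs3, another feedback inhibitor, had 102 ± 94.5 FPKM with IL-33 and 23.3 ± 14.2 with IFN-γ (log2 fold change -1.83 ± 0.71 SE, adjusted p = 0.249, 0.00136 in the blocked fit), and Stat3 did not pass (log2 fold change 0.28, adjusted p = 0.611). Camera called the signalling list higher (adjusted p = 8.45e-04, adjusted p = 0.182 with an estimated correlation).

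Antigen presentation genes rose as well. Of 25 MHC class I and antigen processing genes, 21 rose and none fell with IFN-γ (23 higher, adjusted over the list alone), with a mean log2 fold change of 1.68 (camera adjusted p = 3.78e-29, adjusted p = 0.0498 with an estimated correlation, 0.0842 with that correlation in the blocked fit). Psmb9, an immunoproteasome subunit, rose from 39.2 ± 6.397 to 311 ± 47.1 FPKM, and Psme1, a proteasome activator, from 113 ± 14.9 to 390 ± 23.2 FPKM. The class I gene H2-Q4, whose reads may be shared with related class I genes, had a log2 fold change of 2.28. Of 10 MHC class II presentation genes, 4 rose and none fell (6 higher and 1 lower, adjusted over the list alone). Cd74, the invariant chain, rose from 7.39 ± 3.03 to 94.1 ± 10.4 FPKM (log2 fold change 3.56 ± 0.32 SE, adjusted p = 3.20e-04). H2-Aa, a class II chain, was listed at 0 in all 3 IL-33 libraries and at 15.2, 23.95 and 19.1 FPKM with IFN-γ (adjusted p = 0.00568). The class II list was called higher (camera adjusted p = 1.77e-06, adjusted p = 0.0666 with an estimated correlation). Of 8 chemokines, 3 rose, namely Ccl5, Cxcl9 and Cxcl10 (3 higher, adjusted over the list alone; camera adjusted p = 0.00110, adjusted p = 0.179 with an estimated correlation). Cxcl10, a chemokine that binds CXCR3, was at 2.27, 0 and 1.1 FPKM with IL-33 and at 218, 163 and 126 FPKM with IFN-γ (adjusted p = 0.00294). The Cxcl9 call was lost in 4 of the 9 omissions of a single library, with the highest adjusted p of 0.0958 without IFN-γ replicate 3.

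The main type 2 cytokines of ILC2s were lower with IFN-γ. Il5, which drives eosinophils (chromosome 11, 53534296 to 53538608), fell from 6983 ± 1958 to 2430 ± 922 FPKM (SD, n = 3), a level 2.94-fold lower (log2 fold change -1.55 ± 0.28 SE, adjusted p = 0.0167, 0.00994 in the blocked fit). Il13, which drives mucus production (chromosome 11, 53444826 to 53448204), fell from 7681 ± 2961 to 2997 ± 435 FPKM, 2.46-fold lower (adjusted p = 0.0282, 0.0135 in the blocked fit). Areg, which encodes the tissue repair factor amphiregulin (chromosome 5, 91568641 to 91577458), rose from 82.2 ± 20.9 to 440 ± 297 FPKM (log2 fold change 2.23 ± 0.40 SE, adjusted p = 0.0169). Each of these 3 calls was lost when some single libraries were left out. Over all single-library omissions the log2 fold changes were -1.84 to -1.31 for Il5, -1.52 to -1.01 for Il13 and 1.71 to 2.63 for Areg. The Il5 call was lost without IL-33 replicate 1 (adjusted p = 0.0700), IFN-γ replicate 1 (0.0696) or IFN-γ replicate 2 (0.0780). The Il13 call was lost without IL-33 replicate 1 (0.0700) or 2 (0.0778), without IFN-γ replicate 1 (0.130), 2 (0.0949) or 3 (0.0806), or without IL-27 replicate 2 (0.0582). The Areg call was lost without IL-33 replicate 2 (0.0794) or 3 (0.0523) or IFN-γ replicate 2 (0.0550). Il9 had 2029, 233 and 305 FPKM with IL-33 and 36.5, 42.5 and 108 with IFN-γ (log2 fold change -3.22 ± 0.75 SE, adjusted p = 0.0534, 0.0234 in the blocked fit). Il4 (log2 fold change -0.34, adjusted p = 0.692) and Csf2 (-0.23, adjusted p = 0.892) did not pass. In all, 1 of 16 type 2 products rose and 2 fell (1 higher and 4 lower, adjusted over the list alone), with a camera adjusted p of 0.0103 and adjusted p = 0.354 with an estimated correlation.

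Of 34 ILC2 transcription factors and surface receptors, 1 fell with IFN-γ and 33 did not pass (2 higher and 1 lower, adjusted over the list alone; 5 higher and 6 lower in the blocked fit). The member that fell was Il2ra, the IL-2 receptor α chain (chromosome 2, 11564419 to 11614818), from 928 ± 77.9 to 380 ± 57.1 FPKM (SD, n = 3; log2 fold change -1.29 ± 0.18 SE, adjusted p = 0.00495). The lineage factors Gata3 (log2 fold change 0.13, adjusted p = 0.877) and Rora (0.32, adjusted p = 0.802) did not pass, nor did Klrg1, Kit and Il7r (log2 fold changes 0.02, 0.04 and -0.45). Il1rl1, which encodes the IL-33 receptor, had 569 ± 244 FPKM with IL-33 and 330 ± 94.0 with IFN-γ (log2 fold change -0.74 ± 0.37 SE, adjusted p = 0.387, 0.00486 in the blocked fit). The camera test of this list had an adjusted p of 0.755, with a direction (lower) opposite to its mean and median log2 fold changes of 0.04 and 0.03. Of 11 tested genes of the type 1 lymphocyte programme, 3 rose (4 higher, adjusted over the list alone). Camera called these tested genes higher (adjusted p = 5.82e-04, adjusted p = 0.0565 with an estimated correlation). The list had 22 members, and the untested ones were below the expression filter. Of these, looked up after the call was seen, Cxcr3, Gzma, Gzmb, Gzmc, Fasl, Xcl1 and Klrc1 were listed at 0 in all libraries. Eomes, Il12rb2, Prf1 and Klrd1 had at most 0.3, 0.7, 1.64 and 1.5 FPKM. The filter used all libraries, so Ifng and Tbx21 passed it through the treated groups. Ifng itself was at 0, 0 and 1.0 FPKM with IL-33 and at 10.1, 12.2 and 10.6 with IFN-γ (log2 fold change 3.24 ± 0.43 SE, adjusted p = 0.00320). Tbx21, the gene of the type 1 factor T-bet, was at 0.43, 0 and 0 FPKM with IL-33 and at 9.03, 6.42 and 3.7 with IFN-γ (adjusted p = 0.0385). The Tbx21 call was lost without IL-33 replicate 1, 2 or 3 (adjusted p = 0.0895, 0.124 and 0.0982), without IFN-γ replicate 1, 2 or 3 (0.142, 0.125 and 0.0710) or without IL-27 replicate 2 (0.0663).

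Of 15 regulatory and inhibitory genes associated with IL-27, 4 rose and 1 fell with IFN-γ (4 higher and 1 lower, adjusted over the list alone), and the list was not called (camera adjusted p = 0.564, mean log2 fold change 0.05 and median -0.03). Cd274, the gene of the checkpoint ligand PD-L1, rose from 4.30 ± 1.23 to 30.9 ± 14.6 FPKM (SD, n = 3; adjusted p = 0.00555). Pdcd1, the gene of its receptor PD-1 (chromosome 1, 95934884 to 95949130), fell from 84.2 ± 16.9 to 19.3 ± 3.89 FPKM, 4.18-fold lower (adjusted p = 0.00175). Cd34, a surface sialomucin gene (chromosome 1, 196765015 to 196787486), fell 13.6-fold from 32.6 ± 2.67 to 1.80 ± 1.74 FPKM (log2 fold change -3.77 ± 0.46 SE, adjusted p = 0.00221). Tnfrsf8, which encodes CD30, fell from 89.8 ± 32.1 to 11.1 ± 5.20 FPKM, Adora2b, an adenosine receptor gene, from 32.2 ± 5.99 to 4.89 ± 2.12 FPKM, and Scd2, a fatty acid desaturase gene, from 173 ± 94.6 to 19.7 ± 8.33 FPKM. Of 26 cell death genes, 4 rose and none fell (9 higher and 1 lower, adjusted over the list alone; camera adjusted p = 5.13e-05, adjusted p = 0.0651 with an estimated correlation). They included Casp1, which encodes an inflammatory protease, the necroptosis gene Mlkl, and the death receptor gene Fas, which rose from 6.43 ± 2.12 to 29.0 ± 8.38 FPKM (adjusted p = 0.00409). Bcl2, a survival gene, did not pass (log2 fold change 0.68, adjusted p = 0.445).

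Glycolysis and cholesterol genes were called lower as lists with IFN-γ at the preset correlation. The 20 tested glycolysis genes averaged a log2 fold change of -0.67, of which 2 fell and 18 did not pass (9 lower, adjusted over the list alone and also in the blocked fit; camera adjusted p = 5.42e-08, adjusted p = 0.182 with an estimated correlation). Slc16a3, a lactate exporter gene, fell from 340 ± 89.2 to 119 ± 28.3 FPKM (SD, n = 3), 2.84-fold lower (adjusted p = 0.00805). Of 22 cholesterol synthesis and uptake genes, 6 fell and none rose (12 lower, adjusted over the list alone, 10 in the blocked fit; camera adjusted p = 1.78e-10, adjusted p = 0.0666 with an estimated correlation). Lss, a sterol synthesis gene, fell from 37.4 ± 6.57 to 14.3 ± 3.46 FPKM (adjusted p = 0.00957), a call lost without IL-33 replicate 2 (adjusted p = 0.0526) or IFN-γ replicate 2 (0.0534). Of 17 amino acid stress (ATF4) genes, 1 rose and 2 fell (1 higher and 10 lower, adjusted over the list alone; camera adjusted p = 2.72e-04, adjusted p = 0.0498 with an estimated correlation, 0.111 with that correlation in the blocked fit). Atf3, a stress-induced transcription factor gene, was at 1.72, 0 and 0 FPKM with IL-33 and at 27.4, 25.5 and 20.2 with IFN-γ, whereas Asns, asparagine synthetase, fell from 26.5 ± 4.16 to 6.75 ± 2.03 FPKM. Of 39 proliferation genes, 1 rose (Ccnd3, log2 fold change 0.86) and none fell (1 higher and 1 lower, adjusted over the list alone). Mki67, a marker of cycling cells, did not pass (log2 fold change -0.87 ± 0.28 SE, adjusted p = 0.165, 0.0180 in the blocked fit). The proliferation list had a mean log2 fold change of -0.16 (camera adjusted p = 0.0430, 0.0516 in the blocked fit, and adjusted p = 0.787 with an estimated correlation). The Ccnd3 call was lost in 6 of the 9 omissions of a single library, with the highest adjusted p of 0.1 without IFN-γ replicate 2.

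Lists included as signs of sample handling moved in the same comparison. The 12 immediate early genes averaged a log2 fold change of -1.23 with IFN-γ (camera adjusted p = 5.82e-04, adjusted p = 0.182 with an estimated correlation), with Egr3 the 1 gene that fell, while the abundant Junb and Myc did not pass (log2 fold changes -0.49 and 0.07). The Egr3 call was lost in 4 of the 9 omissions, with the highest adjusted p of 0.0664 without IFN-γ replicate 3. The 8 heat shock genes averaged -0.45 (camera adjusted p = 0.00114, adjusted p = 0.231 with an estimated correlation), with none past the threshold and 4 lower in the blocked fit; for Hspa8 the log2 fold change was -0.18. Among markers of other cell types, Pecam1, which encodes CD31, rose from 64.5 ± 14.7 to 175 ± 25.1 FPKM (SD, n = 3; adjusted p = 0.00495). With Pecam1 as 1 of its 2 tested members, the endothelial list had a camera adjusted p of 0.0436 (0.122 in the blocked fit, and adjusted p = 0.231 with an estimated correlation). Its untested members were looked up after the call was seen. Kdr, Msln, Upk3b, Upk1b, Krt18 and Krt19 were listed at 0 in all libraries. Cdh5 and Tek had at most 0.3 FPKM and Esam at most 1.2 FPKM in any library. The T cell, B cell, macrophage, mast cell and fibroblast lists were not called, with camera adjusted p from 0.448 to 0.857.

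In the IFN-γ comparison limma called 241 genes higher and 79 lower among 11014, and 1696 genes had an unadjusted p under 0.05. The blocked fit called 717 higher and 513 lower, including all 320. With libraries 1 and 2 alone it called 223 and 79, against 109 and 16 without the block. The groups did not overlap for 2265 genes (20.6%), against 10% by chance for 3 libraries against 3 if they are unpaired. Without any single library the counts ranged from 130 to 229 higher, lowest without IFN-γ replicate 2, and from 27 to 70 lower, lowest without the same library. They moved by more than 1.5 times without IL-33 replicate 1 (155 and 38), IL-33 replicate 2 (143 and 34), IFN-γ replicate 1 (159 and 34), 2 (130 and 27) or 3 (140 and 45), and for the lower count also without IL-33 replicate 3 (43) or IL-27 replicate 2 (47). The fit without the block recovered 3.00% of simulated 2-fold changes, and 6.67% among genes with a mean of at least 20 FPKM. Genes that did not pass in that fit may therefore have changed 2-fold. The simulated libraries had no replicate effect, so these shares do not describe the blocked fit.

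**Figure D1:**
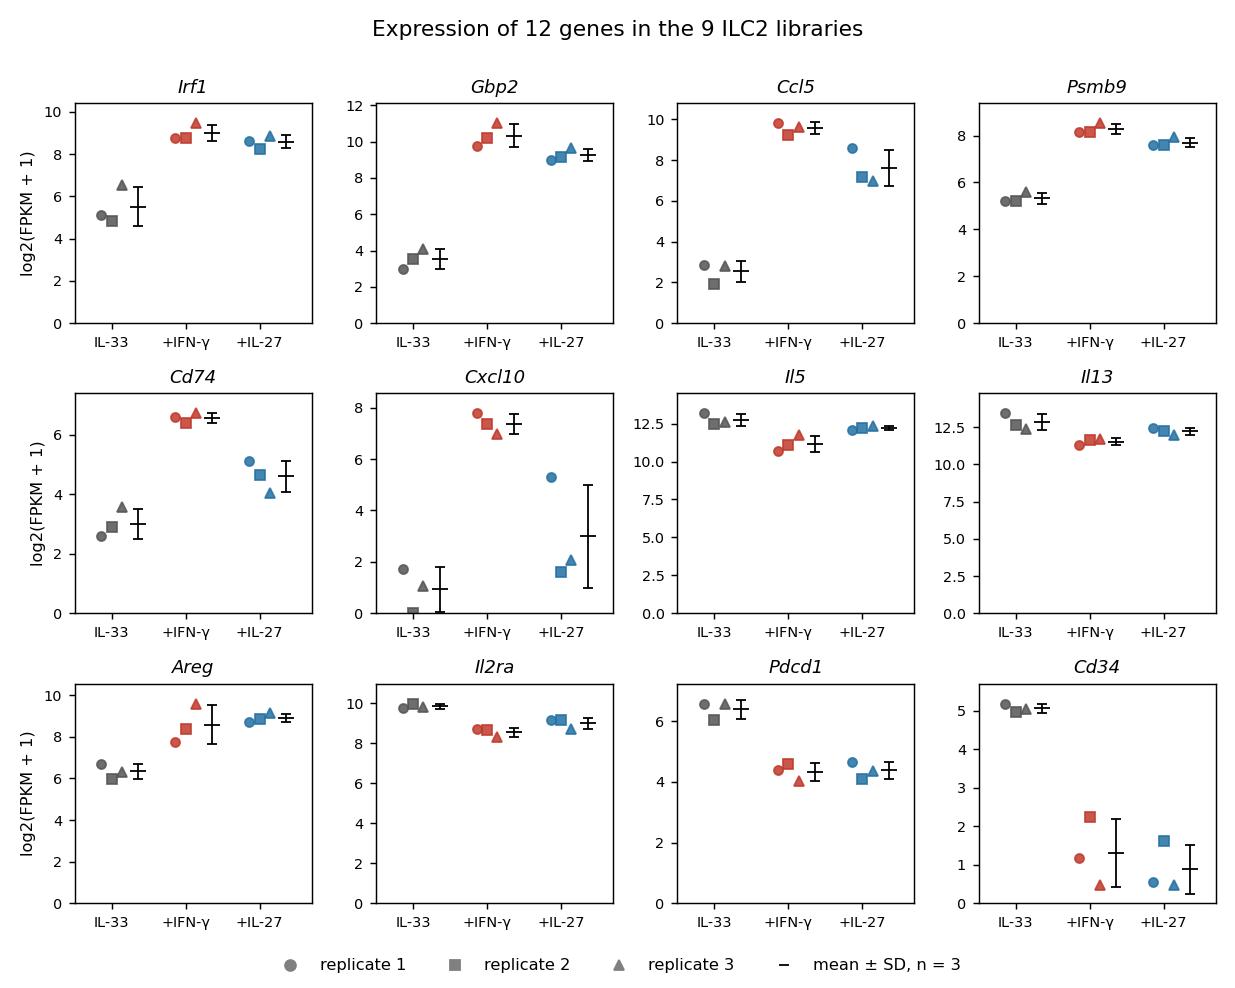
Expression of 12 genes in each library, as log2(FPKM + 1), for IL-33, IL-33 with IFN-γ and IL-33 with IL-27. Circles, squares and triangles are replicates 1, 2 and 3, and bars give the mean ± SD (n = 3); Gbp2 lies at 11.2 ± 4.63 FPKM with IL-33, 1370 ± 617 with IFN-γ and 624 ± 153 with IL-27, and Cd34 at 32.6 ± 2.67, 1.80 ± 1.74 and 0.972 ± 0.943 FPKM.

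The comparison of IL-27 with IL-33 alone asked what IL-27 changed in the same activated cells. Interferon response genes rose here too. Irf1 rose 8.43-fold, from 51.5 ± 36.0 to 388 ± 81.1 FPKM (SD, n = 3; log2 fold change 3.08 ± 0.41 SE, limma adjusted p = 0.00648). Gbp2 rose 52.9-fold, from 11.2 ± 4.63 to 624 ± 153 FPKM (adjusted p = 1.26e-04), and Ccl5 rose 33.4-fold, from 5.06 ± 1.92 to 221 ± 148 FPKM (adjusted p = 4.32e-04). Cd34 fell 18.2-fold, from 32.6 ± 2.67 to 0.972 ± 0.943 FPKM (log2 fold change -4.19 ± 0.46 SE, adjusted p = 0.00231), and Pdcd1 fell 4.04-fold, from 84.2 ± 16.9 to 20.1 ± 4.18 FPKM (adjusted p = 0.00330).

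Of the 21 guanylate-binding proteins and immunity-related GTPases, 18 rose with IL-27 and none fell (19 higher, adjusted over the list alone), with a mean log2 fold change of 3.60 (camera adjusted p = 1.52e-49, adjusted p = 0.0347 with an estimated correlation, 0.0541 with that correlation in the blocked fit). Gbp5 rose 22.6-fold, to 55.7 ± 11.6 FPKM (SD, n = 3), and Iigp1 from 0, 0 and 0.7 to 27.9, 32.0 and 72.3 FPKM. Of 25 MHC class I and antigen processing genes, 15 rose and none fell (23 higher, adjusted over the list alone, 21 in the blocked fit; mean log2 fold change 1.45, camera adjusted p = 2.26e-36, adjusted p = 0.0347 with an estimated correlation, 0.0561 with that correlation in the blocked fit). Psmb9 rose from 39.2 ± 6.397 to 208 ± 30.1 FPKM and Psme1 from 113 ± 14.9 to 303 ± 40.9 FPKM. Of 35 antiviral genes, 10 rose and none fell (26 higher, adjusted over the list alone, 24 in the blocked fit; camera adjusted p = 4.47e-30, adjusted p = 0.0902 with an estimated correlation, 0.0113 with that correlation in the blocked fit). Zbp1 rose from 24.04 ± 14.1 to 287 ± 82.5 FPKM, and Isg20, an exonuclease gene, from 10.9 ± 6.53 to 89.4 ± 30.4 FPKM. Of 23 STAT and IRF signalling genes, 4 rose and none fell (8 higher and 1 lower, adjusted over the list alone; camera adjusted p = 8.03e-04, adjusted p = 0.210 with an estimated correlation). They included Irf1, Irf8 and Irf9, and Irf8 rose from 7.46 ± 2.48 to 45.0 ± 13.4 FPKM. The Irf9 call was lost without IL-33 replicate 1 or 2 (adjusted p = 0.0560 and 0.0654) or IL-27 replicate 1, 2 or 3 (0.0731, 0.0662 and 0.0533). Socs1 had 15.05 ± 1.077 FPKM with IL-27 (log2 fold change 1.35 ± 0.27 SE, adjusted p = 0.0520, 0.0278 in the blocked fit), Socs3 had a log2 fold change of 0.13 (adjusted p = 0.983), and Stat3 one of 0.25 (adjusted p = 0.794). The cytokine receptor subunits were called as a list (camera adjusted p = 0.00672, adjusted p = 0.271 with an estimated correlation) with none of 7 past the threshold and 2 higher adjusted over the list alone; with IFN-γ 1 of the 7, Il12rb1, rose (2 higher, adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.275 with an estimated correlation). The Il12rb1 call with IFN-γ was lost in 5 of the 9 omissions of a single library, with the highest adjusted p of 0.0958 without IFN-γ replicate 3. Il27ra, the IL-27 receptor gene, had log2 fold changes of 0.87 with IFN-γ (adjusted p = 0.0699, 0.0184 in the blocked fit) and 0.78 with IL-27 (adjusted p = 0.192, 0.0426 in the blocked fit).

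Of 10 MHC class II presentation genes, 1 rose with IL-27, the protease gene Ctss, from 3.13 ± 1.32 to 39.5 ± 5.20 FPKM (SD, n = 3; adjusted p = 0.00369), and 3 were higher adjusted over the list alone. Cd74 had 24.3 ± 9.04 FPKM with IL-27 (log2 fold change 1.58 ± 0.32 SE, adjusted p = 0.0520, 0.0352 in the blocked fit), and H2-Aa was listed at 0, 0 and 5.6 FPKM (adjusted p = 0.739). The class II list was called higher (camera adjusted p = 0.0154, 0.0559 in the blocked fit, and adjusted p = 0.271 with an estimated correlation). Of 8 chemokines, Ccl5 rose and 7 did not pass (1 higher, adjusted over the list alone; camera adjusted p = 0.0295, adjusted p = 0.301 with an estimated correlation). Cxcl10 was at 38.0, 2.08 and 3.2 FPKM with IL-27 (log2 fold change 2.07 ± 0.83 SE, adjusted p = 0.457). Of 11 tested type 1 programme genes, Ifng rose to 27.8, 12.1 and 8.6 FPKM (log2 fold change 3.61 ± 0.43 SE, adjusted p = 0.00330), and 3 were higher adjusted over the list alone (camera adjusted p = 0.00654, adjusted p = 0.0902 with an estimated correlation). Tbx21 did not pass (log2 fold change 1.77 ± 0.57 SE, adjusted p = 0.285, 0.0412 in the blocked fit).

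Il5 had 4783 ± 442 FPKM and Il13 4843 ± 834 FPKM with IL-27 (SD, n = 3), and neither passed (log2 fold changes -0.51 and -0.61, adjusted p = 0.632 and 0.494, or 0.331 and 0.199 in the blocked fit). Il9 was at 106, 44.9 and 52.2 FPKM (log2 fold change -3.04 ± 0.75 SE, adjusted p = 0.129, 0.0459 in the blocked fit). Areg rose to 481 ± 68.6 FPKM (log2 fold change 2.56 ± 0.40 SE, adjusted p = 0.0165). Its call was lost without IL-33 replicate 1 or 2 (adjusted p = 0.0515 and 0.101) or IL-27 replicate 1, 2 or 3 (0.0693, 0.0698 and 0.0930). Of 16 type 2 products, Areg alone passed (1 higher and 1 lower, adjusted over the list alone; camera adjusted p = 0.255). None of 34 ILC2 transcription factors and surface receptors passed (1 higher and 1 lower, adjusted over the list alone; 8 higher and 2 lower in the blocked fit; camera adjusted p = 0.291). Il2ra had 522 ± 93.7 FPKM (log2 fold change -0.84 ± 0.18 SE, adjusted p = 0.0795, 0.00509 in the blocked fit), and Gata3 a log2 fold change of 0.43 (adjusted p = 0.666).

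Of 15 regulatory and inhibitory genes associated with IL-27, 2 rose and 1 fell with IL-27 (4 higher and 1 lower, adjusted over the list alone; camera adjusted p = 0.0305, adjusted p = 0.271 with an estimated correlation). Besides Pdcd1, these were Ly6a, the gene of Sca-1, from 1392 ± 262 to 3760 ± 262 FPKM (SD, n = 3), and Ly6c1, whose reads may be shared with Ly6c2. Both calls were lost without IL-27 replicate 3 (adjusted p = 0.0671 and 0.0510). Cd274 had 16.4 ± 5.26 FPKM (log2 fold change 1.70 ± 0.37 SE, adjusted p = 0.0779, 0.0184 in the blocked fit), and Prdm1, the gene of the repressor Blimp-1, did not pass (log2 fold change 0.65, adjusted p = 0.524). Il10, an inhibitory cytokine gene linked to IL-27 and in the fixed set of genes where tested, was below the expression filter, with at most 1.8 FPKM in any library. Gpr128, an adhesion receptor gene, fell from 23.5 to 6.14 FPKM (log2 fold change -1.75, adjusted p = 0.00692). Of 26 cell death genes, 3 rose and none fell (6 higher and 1 lower, adjusted over the list alone, 7 higher in the blocked fit; camera adjusted p = 9.12e-04, adjusted p = 0.0964 with an estimated correlation). These included Casp1 and Mlkl, whose calls were lost in 6 and 9 of the 9 omissions of a single library, with the highest adjusted p of 0.107 and 0.171, each without IL-33 replicate 2. Fas did not pass (log2 fold change 1.21, adjusted p = 0.0978, 0.0166 in the blocked fit).

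No glycolysis gene passed with IL-27 (camera adjusted p = 0.0295, adjusted p = 0.563 with an estimated correlation; mean log2 fold change -0.19; none adjusted over the list alone), and Slc16a3 had a log2 fold change of -0.70 (adjusted p = 0.333). No cholesterol gene of 22 passed either (6 lower, adjusted over the list alone; mean log2 fold change -0.48; camera adjusted p = 4.55e-10, adjusted p = 0.0902 with an estimated correlation). Idi1, a sterol synthesis gene, had the smallest adjusted p of that list (log2 fold change -1.10, adjusted p = 0.0583, 0.00229 in the blocked fit). Of 17 amino acid stress genes, Atf3 rose and Asns fell (1 higher and 4 lower, adjusted over the list alone; camera adjusted p = 0.00166, adjusted p = 0.0902 with an estimated correlation). These calls were lost in 6 and 8 of the 9 omissions of a single library, with the highest adjusted p of 0.107 and 0.187, both without IL-33 replicate 2. No proliferation gene passed (Mki67 log2 fold change -0.41, adjusted p = 0.730; camera adjusted p = 0.146). The immediate early genes averaged -1.10 (camera adjusted p = 2.66e-04, adjusted p = 0.202 with an estimated correlation), all 12 with negative log2 fold changes. Egr3 fell (adjusted p = 0.0192; 2 lower, adjusted over the list alone), and its call was lost in 5 of the 9 omissions, with the highest adjusted p of 0.0901 without IL-27 replicate 3. The heat shock genes averaged -0.48 (camera adjusted p = 3.16e-04, adjusted p = 0.210 with an estimated correlation), with none past the threshold and 4 lower in the blocked fit. The 6 cell type lists tested were not called, with camera adjusted p from 0.146 to 0.846.

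In the IL-27 comparison limma called 100 genes higher and 13 lower, and 1047 genes had an unadjusted p under 0.05. The blocked fit called 371 higher and 196 lower, including all 113. With libraries 1 and 2 alone it called 86 and 10, against 52 and 1 without the block. The groups did not overlap for 1543 genes (14%), against 10% by chance for unpaired libraries. Without any single library the counts ranged from 38 to 109 higher and from 4 to 13 lower. They moved by more than 1.5 times without IL-33 replicate 1 (54 and 8), IL-33 replicate 2 (48 and 8), IL-27 replicate 1 (45 and 4) or IL-27 replicate 3 (38 and 4), and for the higher count also without IFN-γ replicate 2 (61) or IL-27 replicate 2 (57).

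**Figure D2:**
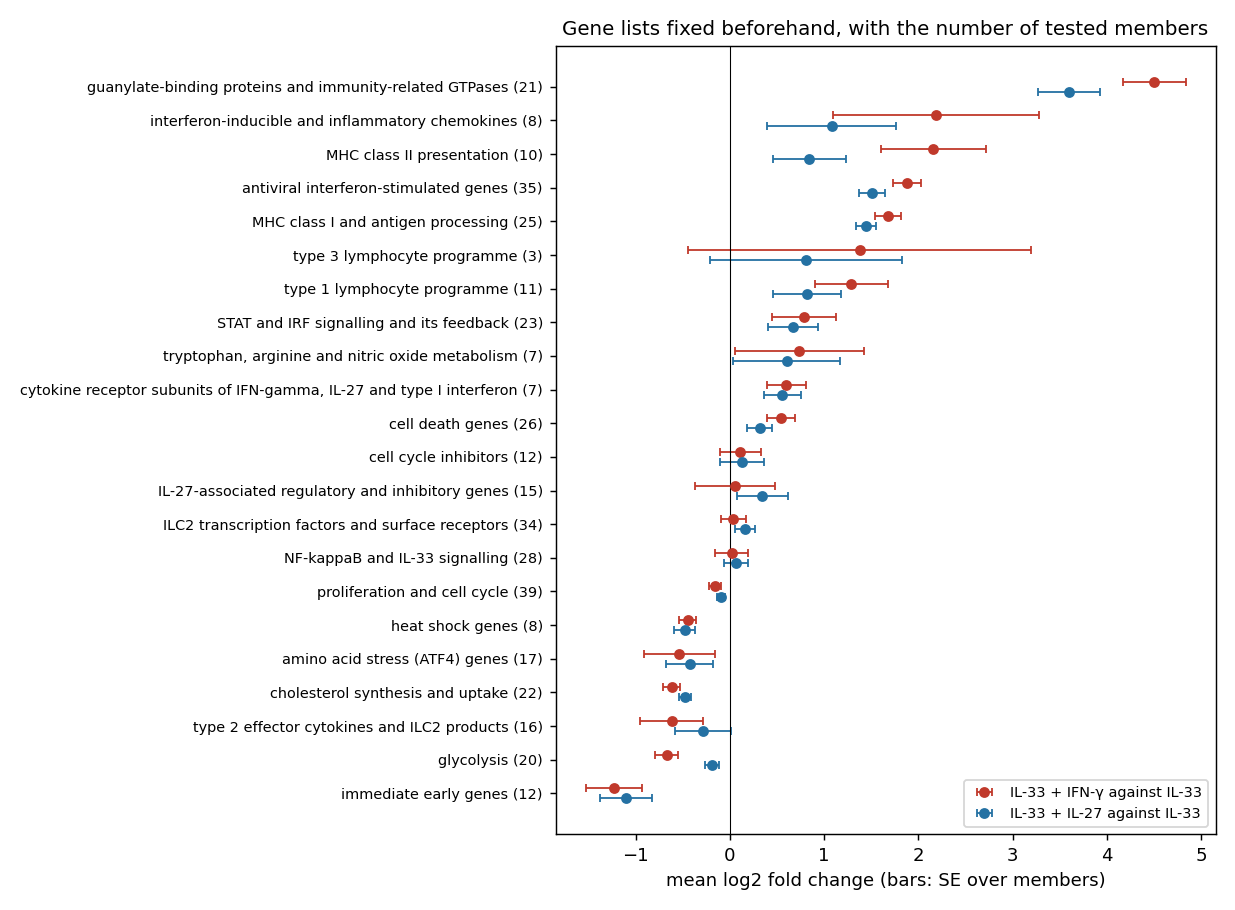
Mean log2 fold change ± SE over the tested members of 22 gene lists, for IFN-γ and for IL-27, each against IL-33 alone. The guanylate-binding protein and immunity-related GTPase list averaged 4.50 with IFN-γ and 3.60 with IL-27, and the glycolysis list -0.67 and -0.19.

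The third comparison asked how far the responses to IFN-γ and IL-27 were shared and where they differed. Of the genes called in each comparison with IL-33, 97 were higher with both cytokines, 12 were lower with both and none was called in opposite directions. The shared genes made up 96.5% of the IL-27 calls. Their number fell from 109 to 40 without IL-27 replicate 3, 47 without IL-27 replicate 1, 63 without IL-27 replicate 2, 54 without IL-33 replicate 2, 59 without IL-33 replicate 1 and 63 without IFN-γ replicate 2. Independent calls would have given 2.19 genes higher and 0.0932 lower with both, but the comparisons share the IL-33 libraries. In 50 simulations without any difference between groups the log2 fold changes correlated at 0.498 across genes on average, against a measured Pearson r of 0.741 across 11014 genes, which are not independent replicates. The covariance of the log2 fold changes was 0.325, against 0.0971 in the simulations. In the blocked fit 324 genes were higher with both, 141 lower with both and 1 opposite, and with libraries 1 and 2 alone 92 changed the same way with both, against 48 without the block. The opposite gene was Pim2, a kinase gene, chosen after its values were seen, with 44.5 ± 19.8 FPKM with IL-33, 82.5 ± 55.7 with IFN-γ and 20.1 ± 10.9 with IL-27 (SD, n = 3; difference of IFN-γ from IL-27 in log2 fold change 1.89, blocked adjusted p = 0.0213).

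**Figure D3:**
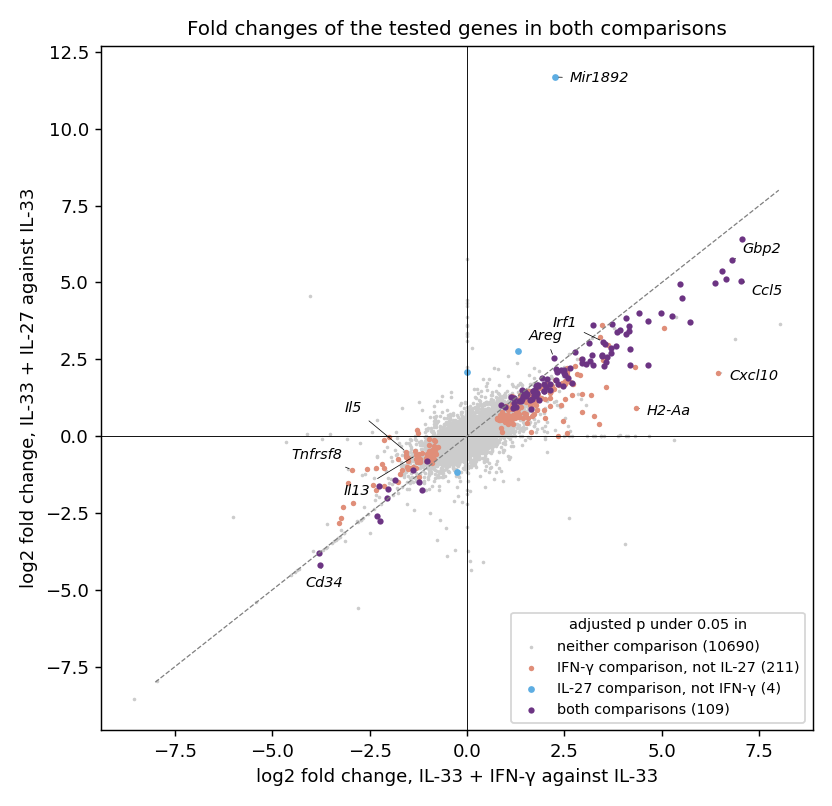
Log2 fold change of each tested gene with IFN-γ (x axis) against that with IL-27 (y axis), each relative to IL-33 alone, on the log2(FPKM + 1) scale. Each point is 1 of 11014 genes, coloured by the comparisons in which it was called, and the dashed line marks equal changes; 109 genes were called in both, and Pearson r was 0.741.

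Compared directly, IFN-γ and IL-27 differed in no single gene by limma (smallest adjusted p = 0.288, 483 genes with an unadjusted p under 0.05). The blocked fit called 6 genes higher and 14 lower with IFN-γ than with IL-27, and 1 and 1 with libraries 1 and 2 alone, as without the block. The 6 included Gbp2 (log2 fold change 1.07, blocked adjusted p = 0.0361), Gbp10 (1.39, 0.0313) and Cxcl10 (4.38, 0.0477). The 14 included Tnfrsf8 (-1.84 ± 0.40 SE without the block, blocked adjusted p = 0.0247), Socs3 (-1.96, 0.0247) and Il1rl1 (-0.91, 0.0361). Differences in the type 2 cytokines did not pass in either fit, with log2 fold changes of -1.04 for Il5 (adjusted p = 0.825, blocked 0.197) and -0.69 for Il13. Class II genes had the largest mean difference among the called lists, 1.31 (Cd74 1.97, blocked adjusted p = 0.0733; H2-Eb1 2.61, blocked adjusted p = 0.0565). Camera called 10 lists as different between the cytokines at the preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.213 (0.181 in the blocked fit). Adjusted over the list alone, 9 guanylate-binding protein and GTPase genes, 3 class II genes, 3 chemokines, 2 type 3 programme genes and 1 gene each of the STAT and IRF, amino acid stress and endothelial lists were higher with IFN-γ. By the same adjustment 1 type 3 programme gene and 1 cell cycle inhibitor were lower. The groups did not overlap for 1050 genes (9.53%), against 10% by chance for unpaired libraries. That value ignores the pairing, and in the blocked fit 1254 genes had an unadjusted limma p under 0.05. Leaving out single libraries gave at most 1 gene higher and 1 lower.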

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

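The tests on single fragments of short features, on T cell markers and on rounding separately for pairs numbered 1 and 2 and pairs numbered 3 were chosen only after the result was seen; the others were planned. Lists of genes are given here because their mean response to IFN-γ differed from that to IL-27 in a camera test of the difference, and each of these calls was lost with an estimated correlation. The values are the mean log2 fold change with IFN-γ minus that with IL-27. The guanylate-binding proteins and immunity-related GTPases differed by 0.904 (means 4.50 and 3.60, camera adjusted p = 7.73e-16, adjusted p = 0.358 with an estimated correlation), and 21 of 21 members were higher with IFN-γ. The MHC class II genes differed by 1.31 (2.16 and 0.845, adjusted p = 3.71e-08, adjusted p = 0.213 with an estimated correlation, 9 of 10 members higher). The chemokines differed by 1.11 (2.19 and 1.08, adjusted p = 0.00217, adjusted p = 0.401 with an estimated correlation, 6 of 8 higher). The antiviral genes differed by 0.368 (1.88 and 1.51, adjusted p = 8.27e-04, adjusted p = 0.597 with an estimated correlation, 31 of 35 higher). The MHC class I genes differed by 0.233 (1.68 and 1.45, adjusted p = 0.00103, adjusted p = 0.505 with an estimated correlation, 22 of 25 higher). The cell death genes differed by 0.222 (0.541 and 0.319, adjusted p = 0.0278, adjusted p = 0.423 with an estimated correlation, 19 of 26 higher). The glycolysis genes differed by -0.478 (-0.668 and -0.190, adjusted p = 2.46e-09, adjusted p = 0.401 with an estimated correlation, 0 of 20 higher). The type 2 products differed by -0.333 (-0.618 and -0.285, adjusted p = 0.00811, adjusted p = 0.505 with an estimated correlation, 5 of 16 higher). The cholesterol genes differed by -0.141 (-0.618 and -0.477, adjusted p = 0.0132, adjusted p = 0.505 with an estimated correlation, 6 of 22 higher). The ILC2 transcription factors and receptors differed by -0.127 (0.0368 and 0.164, adjusted p = 0.0452, adjusted p = 0.613 with an estimated correlation, 11 of 34 higher).

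The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split also mixes libraries of both conditions within each group, so a real difference adds to the spread within groups. Counts from those splits are therefore not a reference without any effect. The real split by IFN-γ gave 320 genes and the highest other split 2, so 1 of 10 splits gave as many. The real split by IL-27 gave 113 genes and the highest other split 3, again 1 of 10. For IFN-γ against IL-27 the real split gave 0 genes and the highest other 1, so 10 of 10 gave as many. In the blocked fit, 4 of the 10 splits part all 3 pairs of equal replicate number, the real one included; the real splits gave 1230, 567 and 20 genes and the highest other of these splits 0, 0 and 1.

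Libraries with the same replicate number deviated together from their group means, at correlations of at least 0.128 over all tested genes. With every library rounded to 1 decimal, as the replicate 3 values are, the lowest same-number correlation was again 0.128, but that pair holds no replicate 3 library, so this test decides nothing. The pairs numbered 1 and 2 hold no rounded library and correlated at 0.128 to 0.367, against -0.115 to -0.0363 for number 1 with number 2. The group means subtracted from them do hold the rounded replicate 3, but this enters both kinds of pair alike. The pairs numbered 3 still correlated at 0.218 to 0.249 among genes with a mean of at least 20 FPKM, against at most 0.0706 for other numbers. These values argue against rounding as the cause for the pairs they cover. Among the 4406 genes with that mean the lowest same-number correlation was 0.0332, so for the weakest pair the shared deviation may sit mainly in genes near the counting limit. A shared cell preparation, culture day or sequencing run remains open, because the labels give none of them and no biological explanation was tested.

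Mir1892, a microRNA gene, was listed at 0, 0.00176 and 0 FPKM with IL-33, at 0, 109 and 0 with IFN-γ, and at 3915, 2041 and 4397 with IL-27 (log2 fold change 11.68, adjusted p = 0.00472). At the full length of 80 nt the largest value would be worth 346 fragments, but the effective length used for so short a feature is unknown, so this is an upper limit and a few fragments may account for it. Whether a single fragment on such a feature counts for over 500 FPKM stays open: the smallest value above 0.5 FPKM of a feature under 110 nt was 0.962, but a value that small is a share of a fragment and does not show what 1 is worth, and the median of the 132 such values was 2193 FPKM. The gene in which it lies, 1110002B05Rik, chosen after the values of Mir1892 were seen, had a log2 fold change of 1.029 with IL-27 (adjusted p = 0.410, 0.0142 in the blocked fit) and of 1.05 with IFN-γ, where Mir1892 did not pass, so a contribution of the host transcript also stays open.

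Ifng, Ccl5 and Ms4a4b, genes that T cells and NK cells express strongly, were higher with both cytokines; Ms4a4b, chosen after its values were seen, was listed at 0 in all 3 IL-33 libraries, at 11.98, 24.1 and 46.5 FPKM with IFN-γ and at 7.34, 9.72 and 25.6 with IL-27. The largest mean log2 fold change of 11 listed T cell markers was 0.199 ± 0.106 SE over markers, below the rise set as a sign of T cells. Of these markers, 3 were listed at 0 in all libraries. Cd3g (28.4 to 97.6 FPKM) and Lat (45.1 to 109 FPKM) were abundant in every library, also with IL-33 alone. The remaining markers, looked up after the values were seen, were low. Cd3d and Cd3e, which encode other CD3 chains, had at most 1.7 and 2.51 FPKM in any library. Cd8b1 had 1.515 to 7.154 FPKM, and Cd8a, Themis and Cd28 at most 0.35, 0.3 and 1.36 FPKM. A small share of T cells in the treated cultures would move the mean over the 11 markers little, so it was not excluded as a source. For NK cells or ILC1s the largest mean was 0.0628 ± 0.0515 SE over 13 markers, again below the set rise. Of these, 8 were listed at 0 in all libraries and 1 passed the expression filter. Gzma, also chosen after its values were seen, was listed at 0 everywhere. Markers at 0 shrink both the mean and its SE, so a small share of these cells was not excluded either. Expression of these genes by the ILC2s themselves remains a hypothesis, found and tested on the same data.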

How the results depend on the processing

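The alternatives without small RNA features, with the block and libraries 1 and 2, with the block and quantile normalization, and with the block and an estimated correlation of list members were chosen only after the result was seen. None of the 121 calls of named genes changed sign in any alternative run, whereas 36 of the 173 results of named genes without a call did in at least 1. Part of this outcome was fixed beforehand. Genes picked for non-overlapping groups cannot change sign when a library is left out or the pseudocount changes. The block by itself leaves every log2 fold change of this balanced design as it was. The block ended no call of a named gene (46 of 294 gene results newly passed and 248 stayed on their side). The pseudocount, a mean of at least 5 FPKM, both scalings and leaving out small RNA features kept every count, the overlap and the correlation within 1.5 times. With the replicate block the calls were 717 higher and 513 lower with IFN-γ, 371 and 196 with IL-27, 6 and 14 in the direct comparison, and 465 shared. With the block and quantile normalization they were 618, 595, 337, 195, 5 and 13, with 453 shared. With the block and libraries 1 and 2 the counts were 223 and 79 with IFN-γ, 86 and 10 with IL-27, 1 and 1 in the direct comparison and 92 shared, against 109, 16, 52, 1, 1, 1 and 48 in the same libraries without the block, with 164 of the 241, 39 of the 79, 60 of the 100 and 5 of the 13 unblocked calls of all libraries kept. With only the 2 groups compared in the fit, 154 and 33 genes were called with IFN-γ, 54 higher with IL-27 and 56 in both. Fewer libraries, and only those of the 2 groups, estimated the spread there, and the reason for the lower counts was not tested. Without a filter the direct comparison gave 1 higher and 1 lower, and without an intensity trend 1 higher and 1 lower, with 8 lower for IL-27; the cause was not tested. Leaving out single libraries or whole replicate numbers gave 13 to 229 higher and 3 to 70 lower with IFN-γ, 4 to 109 higher and 1 to 13 lower with IL-27, 0 to 1 higher and 0 to 1 lower in the direct comparison, and 6 to 115 in both, and Pearson r was 0.660 to 0.791. With fewer libraries the test has less power by construction. All 9 omissions of a single library kept 137 of the 320 IFN-γ calls and 40 of the 113 IL-27 calls. Many of the 84 list tests had no call at the preset correlation and so none to lose. With an estimated correlation 37 calls were lost. Only the guanylate-binding protein and GTPase list and the MHC class I list, with either cytokine, and the amino acid stress list with IFN-γ kept theirs. With that correlation and the block 40 calls were lost, and the antiviral list alone kept its calls with IFN-γ and IL-27. With fry 21 calls were lost and 2 further calls appeared, and with the block at the preset correlation 3 were lost. Depth limits genes near 1.45 to 1.62 FPKM, the worth of 3 fragments in 2 kb.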

Other observations

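Some lists not yet described held single genes that changed. Ltb, which encodes lymphotoxin β and was in the type 3 lymphocyte list, rose from 8.06 ± 6.19 FPKM with IL-33 to 142 ± 57.1 with IFN-γ (SD, n = 3; limma adjusted p = 0.00272) and to 56.1 ± 25.0 with IL-27 (adjusted p = 0.0409). Ido1, the enzyme that breaks down tryptophan, was at 0, 1.38 and 0 FPKM with IL-33, at 11.2, 13.2 and 66.8 with IFN-γ (adjusted p = 0.00564) and at 16.0, 17.2 and 21.4 with IL-27 (adjusted p = 0.0178). Ass1, which makes argininosuccinate, rose with IFN-γ from 35.8 ± 1.995 to 93.9 ± 19.97 FPKM (adjusted p = 0.00907) and had 56.1 ± 11.9 FPKM with IL-27 (adjusted p = 0.358). Rbl2, a cell cycle inhibitor of the retinoblastoma family, rose with IFN-γ from 31.8 ± 5.20 to 75.0 ± 4.80 FPKM (adjusted p = 0.00513) and had 59.1 ± 7.72 FPKM with IL-27 (adjusted p = 0.0529, 0.00389 in the blocked fit). These 4 genes were chosen after their values were seen, and their calls were not examined without single libraries. The lists they belong to were not called, with camera adjusted p of 0.177 and 0.269 for the type 3 list, 0.177 and 0.255 for tryptophan, arginine and nitric oxide metabolism, and 0.661 and 0.291 for cell cycle inhibitors, with IFN-γ and IL-27 in that order. Of 28 NF-κB and IL-33 signalling genes, 3 rose with IFN-γ and 2 with IL-27 (camera adjusted p = 0.448 and 0.292). Relb rose with both, but its call was lost in 5 of the 9 omissions of a single library with IFN-γ (highest adjusted p = 0.0746, without IFN-γ replicate 3) and in 8 with IL-27 (0.148, without IL-27 replicate 1). Nfkbie rose with IFN-γ, with the call lost in 6 (0.0976, without IL-33 replicate 2), and the Icam1 call with IL-27 was lost in all 9 (0.167, without IL-33 replicate 2). Icam1, an adhesion molecule, rose from 25.1 ± 3.42 to 93.1 ± 9.23 FPKM with IFN-γ (adjusted p = 0.00216).

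Ciita, which encodes the master regulator of MHC class II genes, was chosen after its values were seen. It was below the expression filter, which takes the mean over all libraries, with at most 0.8 FPKM in any library. In the IFN-γ libraries, in which H2-Aa and Cd74 rose, it was at 0, 0.193 and 0.8 FPKM, against 0.208, 0 and 0.8 with IL-33. Such values lie below the worth of 3 fragments in 2 kb, so whether Ciita changed could not be judged. Of the 4 genes called with IL-27 and not with IFN-γ, also chosen after their values were seen, Ldhd, a mitochondrial lactate dehydrogenase gene, had 1.31 ± 1.05 FPKM with IL-33, 4.84 ± 2.94 with IFN-γ (adjusted p = 0.164) and 14.1 ± 3.78 with IL-27 (adjusted p = 0.0150). Bin1 had 15.7 ± 0.973, 13.1 ± 2.66 and 6.47 ± 1.61 FPKM (adjusted p = 0.0493 with IL-27), and AU021063 was listed at 0 in the 6 other libraries and at 2.72, 4.92 and 2.5 FPKM with IL-27 (adjusted p = 0.0369). The fourth was Mir1892. None of them passed in the direct comparison without the block. The transcript 2610019E17Rik was listed at 10.7, 19.5 and 10.5 FPKM with IL-33 and at 0 in all 6 treated libraries (adjusted p = 3.46e-04 with IFN-γ and 7.56e-04 with IL-27).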
